A study of Homo sapiens with 6 samples.

How the data were processed

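Total RNA of MCF7 cells, a human breast cancer cell line that expresses the estrogen receptor, was measured on 6 single-colour Affymetrix arrays. All cells had been kept without hormone for 3 days. Of the arrays, 3 (replicates 1 to 3) carry RNA of vehicle-treated cells and 3 carry RNA of cells given 10 µM doxorubicin for 12 hours. Per the labels' protocols, cDNA was primed from the poly(A) tail and copied into biotin-labelled RNA, so that the probe sets mostly read the ends of polyadenylated transcripts. The deposited table holds log2 values by the robust multi-array average (RMA), which corrects background, brings the arrays to a common distribution and summarises the probes of each probe set; RMA and limma are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. Because that step sets a common distribution, a change of total RNA per cell cannot be seen, and each change is relative to the bulk of the probe sets. The table has no detection calls, and no array was left out.

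The table lists 22277 probe sets, of which 62 are control probe sets and 22215 were tested. Of the tested probe sets, 19064 have 1 gene symbol in the platform annotation used here, 1043 have several and 2108 have none. Probe sets with several symbols or none were tested but never named. Through their Entrez identifiers 19052 of the single-symbol probe sets matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. No genome build is named for the array, so no coordinates are given. For each symbol the probe set with the highest mean over all 6 arrays stood for the gene, which gave 11963 genes. Isoforms read by other probe sets are therefore not seen in gene counts. Of 17 genes fixed in advance, TP53 and BBC3 were not analysed here because no probe set carried their symbol alone.

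Doxorubicin was compared with vehicle by limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0): a linear model per probe set with the treatment as its only term, then empirical Bayes moderation of the variance. P-values were adjusted by the Benjamini-Hochberg method, over all probe sets or over all genes, and a gene is called changed at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and spreads are standard deviations (SD) between arrays. Gene lists were tested with the two-sided camera test at a preset correlation between genes of 0.01, adjusted over the 25 lists that were written before the data were examined; the comparison, its tests, the lists and most alternative settings were fixed then. The lists are p53 targets, pro-apoptotic p53 targets, anti-apoptotic genes, estrogen-induced genes, luminal identity genes, G1/S replication genes, G2/M mitosis genes, replication-dependent histones, immediate-early genes, numbered zinc finger genes, cytosolic ribosomal proteins, oxidative phosphorylation genes, proteasome subunits, ribosome biogenesis genes, NF-κB targets, interferon-stimulated genes, unfolded protein and ATF4 genes, NRF2 targets, heat shock genes, cholesterol biosynthesis genes, homologous recombination and Fanconi genes, and markers of stromal, leukocyte, endothelial and basal epithelial cells. They were written from general knowledge, and some share members: 11 of the 16 measured pro-apoptotic p53 targets are also among the p53 targets. Camera was run again with a correlation estimated per list, and the fry test, which asks whether the genes of a list move on balance one way, was a second alternative. Counts of list members are given over all genes tested and adjusted over the list alone.

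The genes named were set by a rule. It takes the 8 largest rises and the 8 largest falls among changed genes without overlap between the groups and with a mean in the higher group at or above 7.32, the median of all probe sets; the 17 fixed genes in any direction; and of each list the up to 3 changed members with the largest change, or, where none changed, the 2 largest, as values only. Members named beyond this rule are marked as chosen after their values were seen. The alternatives were a block for the replicate number, another variance model, quantile normalization of the table again, centring on the array median or on the ribosomal protein genes, array weights, leaving out dim probe sets, a test against a log2 change of 0.5, the mean of all probe sets of a gene, and leaving out each array in turn. Centring on the hybridization controls, which on arrays of this maker are bacterial and phage transcripts added to each hybridization, leaving out both replicate 3 arrays and, for the estrogen-induced list, leaving out each pair of 1 vehicle and 1 doxorubicin array were added after seeing the data.

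The fit was tested on simulated data with the spread of these arrays: 22215 probe sets, 200 changed ones and 40 of a shifted list. It recovered 40.3% of those changed by 0.5 on the log2 scale, 100% at 1 and 98.5% at 2; 6.29% of its calls were false, and 0 calls were made where no change was simulated. The simulated list of 40 genes shifted by -0.4 had a camera p of 5.27e-45 with the preset and 0.000172 with an estimated correlation, and an unshifted list 0.403. Genes were simulated as independent of each other, so this does not test camera on lists whose members move together. The measured G2/M list had an estimated correlation of 0.63. The number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Figures were drawn with matplotlib 3.10.9.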

Results

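The data are 6 expression arrays of hormone-depleted MCF7 cells, 3 from vehicle-treated cells and 3 from cells exposed for 12 hours to 10 µM doxorubicin, an anthracycline that poisons topoisomerase II and breaks DNA. The title of the series concerns the estrogen receptor and p53-dependent apoptosis. The comparison asks which transcripts the drug changed when the receptor had no added hormone. Doxorubicin replicate 3 correlated least with its own group, with a mean Pearson r over probe sets of 0.9912 against 0.9936 to 0.9959 for the other arrays. The 18 hybridization control probe sets had a median of 10.30 ± 0.12 on the doxorubicin and 10.65 ± 0.11 on the vehicle arrays (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Centring on them raised the median change of all probe sets from 0.02 to 0.37, so the changes given here are relative to the bulk of the probe sets.

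Doxorubicin raised genes induced by p53 and lowered genes of DNA replication and mitosis. Among changed genes at or above the median brightness the largest rise was that of TNFRSF10C, a decoy receptor for the death ligand TRAIL, which was 7.84-fold higher, and the largest fall was that of KIF20A, a mitotic kinesin, which was 3.28-fold lower. At an adjusted p under 0.05, 1808 of 22215 probe sets changed, 715 higher and 1093 lower, and 5100 had an unadjusted p under 0.05. Among 11963 genes, 418 rose and 724 fell, of which 49 and 48 changed at least 2-fold. In all 1142 changed genes the doxorubicin and vehicle arrays did not overlap, as in 30.1% of all genes, where chance gives 10%. Of 466 changed genes with several probe sets, 234 had another that changed in the same direction and 2 had one that changed in the opposite direction. The count of probe sets was 631 without vehicle replicate 1, 636 without vehicle replicate 2 and 956 without doxorubicin replicate 2. Centred on the hybridization controls, 13094 were higher and 306 lower.

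Of 48 measured p53 targets, 35 rose and 0 fell, with a median log2 change of 0.96. TNFRSF10C went from 7.06 ± 0.64 to 10.04 ± 0.16 (log2, SD, n = 3 each; change 2.97, SE 0.26, adjusted p = 0.0006). TP53I3, a p53-induced oxidoreductase, rose by 2.63 (SE 0.32, adjusted p = 0.00191), and TNFRSF10B, a death receptor for TRAIL, rose by 2.45 (SE 0.11, adjusted p = 2.17e-05), or 5.47-fold. TP53I3 reached 11.74 on doxorubicin replicate 3 against 10.17 and 10.54 on replicates 1 and 2. The cell cycle inhibitor CDKN1A was 2.82-fold higher, at 12.44 ± 0.05 against 10.94 ± 0.46 (SD, n = 3 each; adjusted p = 0.00224). MDM2, the ubiquitin ligase that degrades p53, was 2.12-fold higher (log2 change 1.08, SE 0.10, adjusted p = 0.000771). GADD45A, a DNA damage-induced growth arrest gene, rose by 1.99 on the log2 scale, TIGAR, a regulator of glycolysis, by 1.90, SESN1, a stress-induced inhibitor of mTOR signalling, by 1.69, and GDF15, a secreted stress factor, by 1.67, with adjusted p from 4.92e-05 to 0.00623. Of these targets, 37 rose and 0 fell when adjusted over the list alone. The list's shift against all other genes had a camera adjusted p of 4.86e-31 over 25 lists, and adjusted p = 0.0642 with an estimated correlation.

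Among 16 measured pro-apoptotic p53 targets 10 rose and 1 fell, with a median log2 change of 0.75. The counts were 10 and 2 adjusted over the list alone. Of these 16, 11 are also among the p53 targets. Together both lists hold 36 genes that rose, against 35 for the p53 targets alone. This rise is therefore mostly that of the same genes. The death receptor FAS was 4.75-fold higher, at 8.48 ± 0.64 against 6.23 ± 0.22 (SD, n = 3 each; log2 change 2.25, SE 0.27, adjusted p = 0.00171). BAX, which permeabilises mitochondria, was 2.33-fold higher (SE 0.17 on the log2 scale, adjusted p = 0.00326). PMAIP1, which encodes the BH3-only protein NOXA, was 2.42-fold higher (SE 0.23, adjusted p = 0.0104). Its adjusted p was 0.0503 without vehicle replicate 1 and 0.062 without vehicle replicate 2. TNFRSF10C, TP53I3 and TNFRSF10B led this list too, and the first of them is a decoy that carries no death domain. The member that fell was BID, a BH3-only protein, by 0.51 on the log2 scale (SE 0.12, adjusted p = 0.0306). It was chosen after its value was seen, and 0 members fell without vehicle replicate 1 or 2 or without doxorubicin replicate 1 or 2. Without vehicle replicate 3, 2 fell, BID and BAK1, a pore-forming protein of mitochondria, by 0.59 and 0.42 (adjusted p = 0.0338 and 0.0375; BAK1 too was chosen after its value was seen). The list's camera adjusted p was 3.42e-07, and adjusted p = 0.175 with an estimated correlation. Of 11 anti-apoptotic genes 0 rose and 1 fell (1 and 1 adjusted over the list alone). Without adjustment 2 and 2 passed, and without doxorubicin replicate 3, 1 rose. BIRC5, which encodes survivin and is also in the mitosis list, fell by 0.76 (SE 0.12, adjusted p = 0.00481). BCL2 stood at 7.60 ± 0.05 with doxorubicin and 7.50 ± 0.35 with vehicle (SD, n = 3 each; adjusted p = 0.752). The anti-apoptotic list had a median of 0.10, a mean of -0.01 and a camera adjusted p of 0.871. Leaving out 1 array gave medians from -0.06 to 0.16 and changes of BCL2 from -0.06 to 0.29, lowest without vehicle replicate 3 and highest without vehicle replicate 2.

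**Figure D1:**
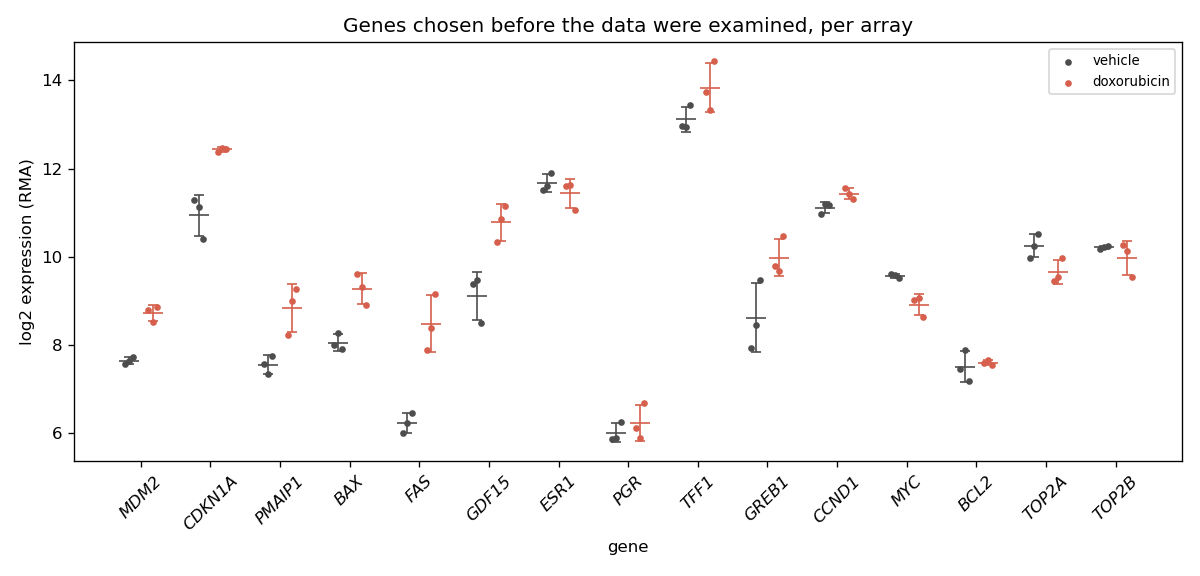
Log2 expression (vertical axis) of the 15 analysed genes that were fixed in advance (horizontal axis), with 1 point per array, and the mean and SD of the 3 vehicle (grey) and 3 doxorubicin (red) arrays. MDM2, CDKN1A, PMAIP1, BAX, FAS and GDF15 lie higher on every doxorubicin array, while ESR1, PGR, TFF1, BCL2 and TOP2B overlap between the groups.

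Mitotic genes fell most broadly. Of 52 measured G2/M genes, 41 fell and 0 rose, with a median log2 change of -0.79. With p-values adjusted over the list alone 47 fell and 0 rose. KIF20A went from 9.58 ± 0.22 to 7.86 ± 0.52 (SD, n = 3 each; change -1.71, SE 0.23, adjusted p = 0.00256). NDC80, a kinetochore component, fell by 1.61 (SE 0.18, adjusted p = 0.00157), and PLK1, a mitotic kinase, fell by 1.59 (SE 0.12, adjusted p = 0.000248). On doxorubicin replicate 3 the median of the list lay 0.55 below the vehicle mean, against 0.93 and 0.88 on replicates 1 and 2. The list's camera adjusted p was 7.7e-32, and adjusted p = 0.31 with an estimated correlation. The other largest falls were those of KIF14, a kinesin of cytokinesis, H2AX, a histone variant, E2F8, a repressor of cell cycle transcription, TIPIN, a replication fork protein, and KCNJ8, a potassium channel. Their log2 changes were -1.51, -1.50, -1.47, -1.44 and -1.44, with adjusted p from 4.92e-05 to 0.00509.

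Replication genes fell as well. Of 43 measured G1/S genes 27 fell and 2 rose, with a median log2 change of -0.48, and 32 and 3 adjusted over the list alone. Components and partners of the replicative helicase led, with MCM6 lower by a log2 change of -1.12 (SE 0.10, adjusted p = 0.000639), MCM10 of -1.05 (SE 0.10, adjusted p = 0.000755) and MCM3 of -0.95 (SE 0.11, adjusted p = 0.00155). Against the rest, PCNA, the sliding clamp of DNA polymerases, rose by 0.66 and TYMS, thymidylate synthase, by 0.52 (adjusted p = 0.0115 and 0.0113; both chosen after their values were seen). The camera adjusted p of the list was 7.03e-17, and adjusted p = 0.149 with an estimated correlation. TOP2A, the drug's target in dividing cells, stood at 9.66 ± 0.27 against 10.25 ± 0.26 and TOP2B at 9.98 ± 0.39 against 10.22 ± 0.03 (SD, n = 3 each; adjusted p = 0.051 and 0.422). Without doxorubicin replicate 3 the adjusted p of TOP2A was 0.0102. Without vehicle replicate 1, 16 G1/S genes fell and 0 rose, without vehicle replicate 2, 16 fell, and centred on the hybridization controls 13 fell and 5 rose.

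Among 34 homologous recombination and Fanconi genes 13 fell and 0 rose, with a median log2 change of -0.33 that became 0.02 when centred on the hybridization controls. H2AX, which is phosphorylated at DNA breaks, went from 12.63 ± 0.08 to 11.13 ± 0.03 (SD, n = 3 each; 2.82-fold lower, adjusted p = 4.92e-05). CHEK1, a checkpoint kinase, fell by 0.86 (SE 0.15, adjusted p = 0.00785), and BRIP1, a helicase that partners BRCA1, by 0.82 (SE 0.17, adjusted p = 0.0195, and 0.0544 without doxorubicin replicate 2). When adjusted over the list alone, 20 fell and 1 rose. For the list as a whole the camera adjusted p was 1.97e-10, and adjusted p = 0.113 with an estimated correlation. Without vehicle replicate 1, 7 fell, and without vehicle replicate 2 or doxorubicin replicate 2, 8 fell. Of 41 replication-dependent histone genes 1 rose and 2 fell, also adjusted over the list alone, and 3 and 3 without doxorubicin replicate 3 or 1 and 4 without vehicle replicate 3. H2AC25 rose by 0.78, H1-3 fell by 0.78 and H1-4 fell by 0.66 (adjusted p from 0.00141 to 0.00503). The histone list had a median of -0.03 (-0.06 to 0.00 without 1 array) and a camera adjusted p of 0.4. Since cDNA was primed from the poly(A) tail, histone transcripts without such a tail would mostly be missed. With dim probe sets left out, 19 of the 41 genes remained. The flat list therefore does not show that histone transcripts stayed level.

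Of 41 genes that estrogen is known to induce, 7 rose and 1 fell in the hormone-depleted cells, with a median log2 change of 0.22. FOS, an immediate-early transcription factor, was 3.00-fold higher (SE 0.15 on the log2 scale, adjusted p = 0.00081), and the chemokine CXCL12 was 2.32-fold higher (SE 0.12, adjusted p = 0.000863). GREB1, a cofactor of the estrogen receptor, stood at 9.98 ± 0.43 against 8.62 ± 0.78 (SD, n = 3 each; adjusted p = 0.0376), and leaving out any 1 of the 5 arrays other than vehicle replicate 3 ended its call, with adjusted p from 0.0634 to 0.146. CCN5, TFF3, CTSD and ADCY9 also rose, and MYC fell by 0.66 (SE 0.12, adjusted p = 0.0101; 0.054 without vehicle replicate 1 and 0.0521 without vehicle replicate 2). CCN5, CTSD and ADCY9 were chosen after their values were seen. ESR1, which encodes the receptor, stood at 11.44 ± 0.33 against 11.68 ± 0.20, its target PGR at 6.23 ± 0.42 against 6.01 ± 0.22, TFF1 at 13.84 ± 0.55 against 13.11 ± 0.29 and CCND1 at 11.43 ± 0.12 against 11.12 ± 0.13 (SD, n = 3 each). Their adjusted p were 0.417, 0.527, 0.101 and 0.0873, and without doxorubicin replicate 2 the adjusted p of TFF1 was 0.0429. The change of PGR, 0.22, was -0.01 without doxorubicin replicate 3 and 0.40 without doxorubicin replicate 2. Adjusted over the list alone 7 rose and 2 fell, and the camera adjusted p was 0.0016, with adjusted p = 0.563 with an estimated correlation. Without doxorubicin replicate 3 the median was 0.12. In turn, 4 members rose without doxorubicin replicate 1 or 2, and 3 without vehicle replicate 1 or 2.

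Luminal identity genes moved both ways, with 3 of 22 higher and 3 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.371). The transcription factors TFAP2C and ELF3 rose by 0.64 and 0.54, and the secreted peptide TFF3 by 0.62 (adjusted p = 0.00195, 0.00809 and 0.0242). GATA3, MUC1 and KRT18 fell by 0.50, 0.51 and 0.34 (adjusted p = 0.0496, 0.0261 and 0.0253; chosen after their values were seen). Centred on the hybridization controls the change of KRT18 was 0.01. The TFF3 call was lost without vehicle replicate 1 or 2 or doxorubicin replicate 1 or 2, with adjusted p from 0.0674 to 0.109, and in those fits 2 members rose and 0 fell. Without vehicle replicate 3, 1 fell.

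**Figure D2:**
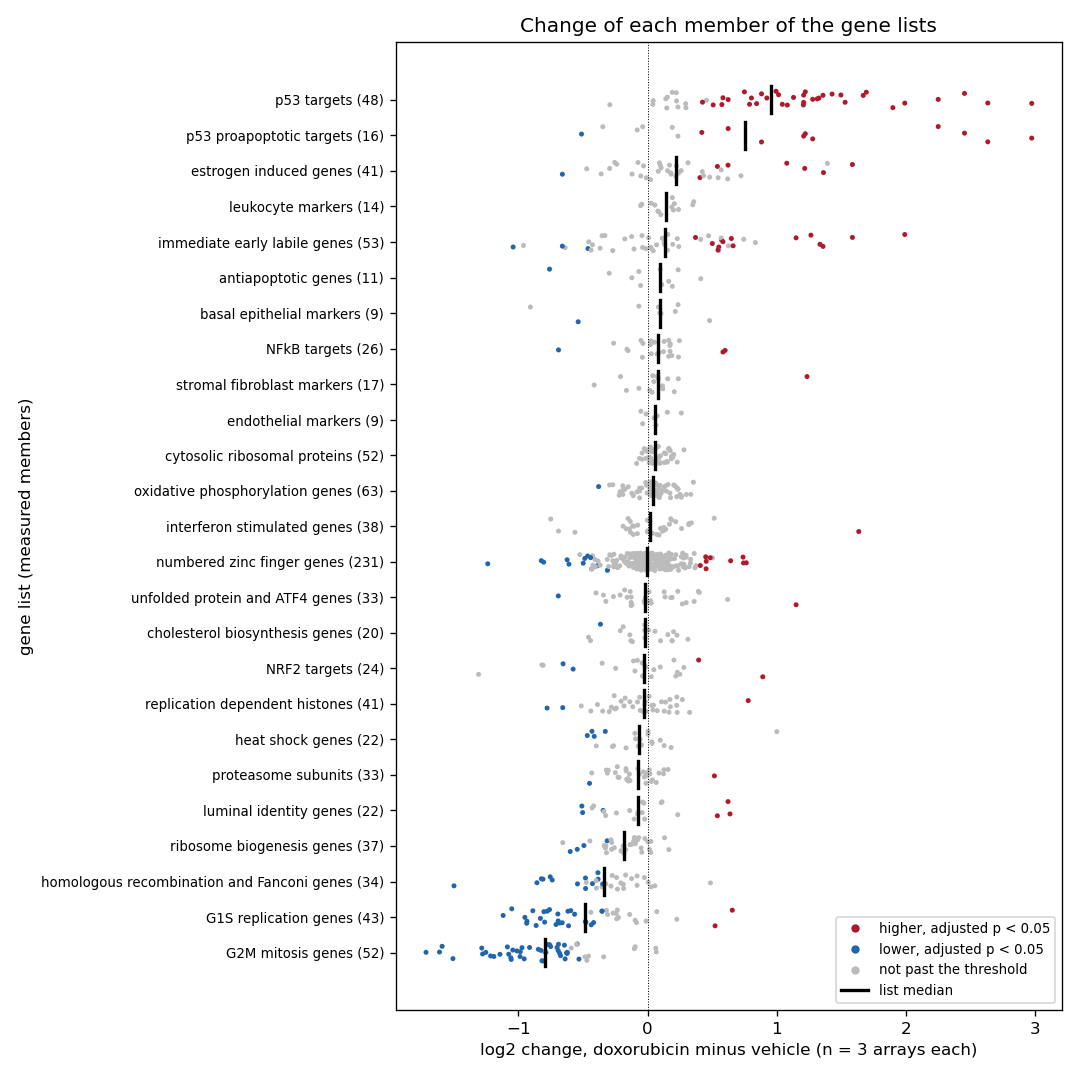
Log2 change, doxorubicin minus vehicle (horizontal axis, 3 arrays each), of every measured member of the 25 gene lists (vertical axis, sorted by median). Red and blue points passed an adjusted p of 0.05, and black bars are list medians. The p53 targets have a median of 0.96 and the G2/M genes of -0.79. The medians of homologous recombination and of ribosome biogenesis genes, -0.33 and -0.18, turn to 0.02 and 0.17 when the arrays are centred on the hybridization controls, as do all smaller negative medians.

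Immediate-early genes, whose transcripts are short-lived, included 14 of 53 that rose and 3 that fell, with a median log2 change of 0.13. GADD45A and FOS led, followed by IER5, which rose by 1.36 (SE 0.17, adjusted p = 0.00191). MYC, SOCS2 and DUSP2 fell by 0.66, 1.04 and 0.46, the last 2 chosen after their values were seen. Counted as adjusted over the list alone, 19 rose and 6 fell. For this list the camera adjusted p was 0.0032, with adjusted p = 0.564 with an estimated correlation. It was 0.107 without doxorubicin replicate 2, where 9 rose and the median was 0.08. Without vehicle replicate 1 or 2, 7 rose and 0 fell, and without vehicle replicate 3, 9 rose and 5 fell. Of 26 NF-κB targets 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.19). Of these, NFKBIE and IER3 rose by 0.60 and 0.58, and REL fell by 0.69. Leaving out any 1 vehicle array or doxorubicin replicate 1 ended the NFKBIE call (adjusted p from 0.0504 to 0.153). The call of IER3 was lost without vehicle replicate 1 or 2 (0.0595 and 0.0677), as was that of REL without vehicle replicate 2 (0.0643).

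Other stress programmes changed in few members. TAP1, the peptide transporter of antigen presentation, was the 1 of 38 interferon-stimulated genes that rose, 3.10-fold (SE 0.17 on the log2 scale, adjusted p = 0.00114), and 0 fell. Unadjusted, 4 rose and 2 fell, adjusted over the list alone 1 and 0, and without doxorubicin replicate 2, 5 fell (camera adjusted p = 0.54). The median of the list was 0.02, and leaving out 1 array gave from -0.10 without that one to 0.11 without doxorubicin replicate 1. Of 33 unfolded protein and ATF4 genes 1 rose, ATF3 by 1.15, and 1 fell, CEBPG by 0.69 (adjusted p = 0.00268 and 0.00589). The counts were 1 and 1 adjusted over the list alone. Without doxorubicin replicate 1 or 3, 2 rose, and without vehicle replicate 3, 2 fell. The list's median was -0.02 (-0.06 to 0.04 without 1 array) and its mean 0.03, and the test pointed up with an adjusted p of 0.802. Among 24 NRF2 targets the detoxifying enzyme EPHX1 rose by 0.89 and TXNRD1, chosen after its value was seen, by 0.40, while ME1 and UGDH fell by 0.65 and 0.58 (adjusted p from 0.00114 to 0.0184). Among them 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.802). The number that rose was 1 without doxorubicin replicate 2 or any 1 vehicle array, and 4 fell without doxorubicin replicate 3. Of 22 heat shock genes 4 fell and 0 rose (5 and 0 adjusted over the list alone, 6 and 1 unadjusted). They were DNAJB1, HSPA2, HSPA9 and BAG3, with falls from 0.33 to 0.47, BAG3 chosen after its value was seen, which was 0.03 when centred on the hybridization controls. The count was 0 without vehicle replicate 1 or 2 or doxorubicin replicate 1 or 2, and 2 without vehicle replicate 3. The camera adjusted p of the heat shock list was 0.0823, and 0.00612 without doxorubicin replicate 3.

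Of 37 ribosome biogenesis genes 4 fell and 0 rose, with a median log2 change of -0.18 that became 0.17 when centred on the hybridization controls. RRP1B, a nucleolar processing factor, fell by 0.60, the helicase DDX10 by 0.54, PES1, needed for the large subunit, by 0.49, and GAR1, a component of snoRNA particles chosen after its value was seen, by 0.31 (adjusted p from 0.00588 to 0.0405). The change of GAR1 was 0.04 on that scale. As adjusted over the list alone, 10 fell and 0 rose (12 and 0 unadjusted). Its camera adjusted p was 3.19e-05, with adjusted p = 0.563 with an estimated correlation. The number that fell was 1 without vehicle replicate 1, 2 without vehicle replicate 2 or doxorubicin replicate 1 or 2, and 8 without vehicle replicate 3 or doxorubicin replicate 3, and the median was -0.10 without vehicle replicate 2 and -0.12 without doxorubicin replicate 1. Cytosolic ribosomal protein genes had a median of 0.06 (0.03 and 0.09 without doxorubicin replicates 1 and 3), and 0 of 52 rose or fell, also adjusted over the list alone, by limma (5 and 0 unadjusted). Their camera adjusted p was 0.0175, with adjusted p = 0.692 with an estimated correlation and from 0.0764 to 0.102 without vehicle replicate 1, doxorubicin replicate 1 or doxorubicin replicate 2. RPS19 and RPS24 had the largest values, 0.28 and 0.23 (adjusted p = 0.0576 and 0.114).

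Proteasome subunits had 1 of 33 that rose, the immunoproteasome subunit PSMB10 by 0.52 (adjusted p = 0.00593), and 1 that fell, the core subunit PSMB1 by 0.45 (adjusted p = 0.0213; 1 and 1 adjusted over the list alone). The camera adjusted p of this list was 0.152, but without doxorubicin replicate 3 it was 2.44e-05, and 8 members fell. PSMB1 was not called without vehicle replicate 1 or 2 or doxorubicin replicate 1 or 2, with adjusted p from 0.0694 to 0.0939. Of 63 oxidative phosphorylation genes 0 rose and 1 fell, NDUFV2 of complex I by 0.38 (adjusted p = 0.0186). None (0) passed adjusted over the list alone, and unadjusted 5 rose and 4 fell (camera adjusted p = 0.331). The median of the list was 0.25 on doxorubicin replicate 3 but -0.05 and -0.03 on replicates 1 and 2. Over all arrays the median was 0.04. It was 0.11 and 0.08 without doxorubicin replicates 1 and 2. Without doxorubicin replicate 3 it was -0.04 and 7 members fell, and without doxorubicin replicate 1 their camera adjusted p was 0.0242. The call of NDUFV2 was lost without vehicle replicate 1 or 2 or doxorubicin replicate 2 (adjusted p from 0.0645 to 0.0758). Of 20 cholesterol biosynthesis genes 0 rose and 1 fell, the kinase PMVK by 0.36 (adjusted p = 0.0209). Adjusted over the list alone the counts were 0 and 1, unadjusted 0 and 3, and 4 fell without doxorubicin replicate 3 (camera adjusted p = 0.756). The call of PMVK was lost without vehicle replicate 1 or 2 or doxorubicin replicate 1 or 2 (adjusted p from 0.0547 to 0.0942). The 231 numbered zinc finger genes, which served as a broad class of dim, short-lived transcripts, had a median of 0.00, and 9 rose and 12 fell (10 and 14 adjusted over the list alone, camera adjusted p = 0.871). The largest changes were in ZNF165, ZNF467 and ZNF184, of -1.24, -0.82 and -0.80. Leaving out 1 array gave 3 to 10 that rose and 2 to 11 that fell, lowest without vehicle replicate 1, and leaving out any 1 vehicle array ended the call of ZNF184 (adjusted p from 0.0894 to 0.135).

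Markers of other cell types gave few calls. Of 17 stromal markers 1 rose and 0 fell (2 and 1 unadjusted, 1 and 0 adjusted over the list alone, camera adjusted p = 0.328). Fry, which does not compare a list with other genes, called this list higher (adjusted p = 0.0125), with a median of 0.08 that was 0.05 and 0.04 without doxorubicin replicates 1 and 3. The member that rose, ACTA2, smooth muscle actin, was 2.35-fold higher (adjusted p = 0.000308). The 14 leukocyte markers had 0 rises and falls by limma, also adjusted over the list alone (3 and 0 unadjusted), and a median of 0.15 with a camera adjusted p of 0.0455. The adjusted p was 0.64 with an estimated correlation. It was 0.267 without doxorubicin replicate 3, where the median was 0.06, and 0.0764 and 0.0704 without vehicle replicates 1 and 2. CD2 and MS4A1 had the largest values of this list, 0.36 and 0.35 (adjusted p = 0.0894 and 0.0699; 0.0451 for MS4A1 without doxorubicin replicate 1). Of 9 endothelial markers 0 rose or fell by limma, unadjusted too and adjusted over the list alone (median 0.06, and 0.02 to 0.09 without 1 array; camera adjusted p = 0.54), with values of 0.26 for TEK and 0.15 for EMCN. Of 9 basal epithelial markers 0 rose and 1 fell, ITGB4 by 0.54 (adjusted p = 0.0206). Adjusted over the list alone the counts were 0 and 1, and unadjusted 1 and 2. The ITGB4 call was lost without vehicle replicate 1 or 2 (adjusted p = 0.0863 and 0.0952), and 2 fell without doxorubicin replicate 1. The median of this list was 0.09 (0.04 without doxorubicin replicate 1), its mean -0.03 and its camera adjusted p 0.798. As signs of RNA quality, the 3′ minus 5′ difference of the GAPDH control probe sets was 0.106 ± 0.022 with doxorubicin and 0.158 ± 0.009 with vehicle, and that of ACTB 0.210 ± 0.052 and 0.177 ± 0.034 (SD, n = 3 each; two-sided exact permutation p = 0.1 and 0.4, where 0.1 is the smallest possible). The control probe set for 28S ribosomal RNA stood at 10.06 ± 0.30 with doxorubicin and 10.94 ± 0.36 with vehicle (SD, n = 3 each; two-sided exact permutation p = 0.1), without overlap.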

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

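No list test, and no gene named by the rule, that was past its threshold in either fit changed direction under any setting run. For the list tests the centring settings could hardly show a turn. They move all genes of an array alike, and camera compares a list with the other genes. Centring on the hybridization controls turned the medians of several called lists, as given with them, and the direction of 48 of the 1142 changed genes, among them KRT18, GAR1 and BAG3 (0.01, 0.04 and 0.03). Among genes and lists past the threshold in neither fit, 4 genes (ESR1, PGR, BCL2 and TOP2B) and 10 lists changed direction under some setting. Centring on the hybridization controls and leaving out both replicate 3 arrays, or other pairs of 1 vehicle and 1 doxorubicin array, were chosen after seeing the data. The count of changed probe sets (1808) and of genes (1142) stayed within 1.5 times under the replicate block, the other variance model, repeated quantile normalization, centring on the array median or on ribosomal protein genes, and without dim probe sets. Array weights gave 2860 probe sets (1193 higher, 1667 lower) and 1761 genes. Centring on the hybridization controls gave 13400 (13094 higher, 306 lower) and 7028 genes, since that scale adds about 0.35 to each change. Without both replicate 3 arrays 2822 probe sets changed, 1187 of them higher; the cause was not tested. The test against a log2 change of 0.5 left 58 (38 higher, 20 lower), as its larger null allows. Leaving out 1 array gave from 631 to 2168 probe sets (254 to 894 higher, 377 to 1274 lower) and from 411 to 1348 genes, with fewer arrays. Over all probe sets the replicate numbers showed little pairing: deviations of same-numbered arrays correlated at 0.017, 0.142 and 0.035. Vehicle replicate 3 and doxorubicin replicate 1 correlated better with each other, at 0.069, than with their own numbers. All other differently numbered pairs of vehicle and doxorubicin arrays lay from -0.112 to -0.004, below the same-numbered pairs, so weak pairing is not excluded. A shared effect on some genes of both replicate 3 arrays is not excluded, since the estrogen-induced list lay higher on both. The replicate block gave 1587 probe sets, 1394 of them shared with the fit without it.

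With an estimated correlation 0 of 25 lists passed (4 at an unadjusted p under 0.05), against 10 with the preset one. The adjusted p were 0.0642 for p53 targets, 0.175 for pro-apoptotic p53 targets and 0.563 for estrogen-induced genes. They were 0.149 for G1/S genes, 0.31 for G2/M genes and 0.113 for homologous recombination genes. Fry called 6 lists, the stromal markers and the lists just named other than the estrogen-induced genes, which it gave 0.104. The cause was not tested. Correlation between genes does not account for all of the loss with an estimated correlation. In the simulation, where genes were independent, the camera p of the shifted list also went from 5.27e-45 to 0.000172. NF-κB targets had an estimate of 0.00662, under the preset 0.01, and their unadjusted camera p still went from 0.0988 to 0.163. Of 61 named genes past the threshold, 43 kept it in all 6 fits that left out 1 array and 18 lost it in at least 1; centring on the hybridization controls ended the call of 16. The arrays give no background level, so what dim probe sets limit is unknown.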

Other observations

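Chosen only after the result was seen were the 8 further lists described here, which were written when the genes with the largest changes were known, the settings without both replicate 3 arrays and without other pairs of 1 vehicle and 1 doxorubicin array, and the tests of hormone exposure, RNA quality, response strength and short-lived transcripts. Genes named here that the rule does not name, IFI27 and IFI6 among them, were chosen after their values were seen. Of 16 measured genes of MHC class I antigen presentation 9 rose and 0 fell, with a median log2 change of 0.40 (12 and 0 unadjusted). TAP1 rose by 1.63, HLA-C by 0.74, B2M, the light chain of class I molecules, by 0.69, and PSMB10, an immunoproteasome subunit, by 0.52 (SE 0.17, 0.13, 0.14 and 0.08). Probe sets for HLA genes can read related transcripts, and 4 of the 16 members stand in another list. The list's camera adjusted p over these 8 lists was 1.54e-07, and adjusted p = 0.0589 with an estimated correlation; without vehicle replicates 1 or 2 or doxorubicin replicate 2 the number that rose was 4, 3 and 3. Leukocyte markers, which share the direction, had a median of 0.15. Lysosome and autophagy genes had 6 of 31 higher and 0 lower (10 and 1 unadjusted; median 0.18, camera adjusted p = 0.000836, and adjusted p = 0.341 with an estimated correlation), led by the proton pump subunit ATP6V1A, by 0.59, and the protease ATG4A, by 0.58. That count was 0 without vehicle replicate 1, and 2 without vehicle replicate 2 or 3 or doxorubicin replicate 2.

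Of 29 genes of the nuclear envelope, lamins and nuclear pore proteins among them, 8 fell and 0 rose (10 and 1 unadjusted), with a median of -0.17 that became 0.19 when centred on the hybridization controls. LMNB1, a lamin whose loss is used as a marker of senescence, fell by 1.23, LMNB2 fell by 0.70 and the pore protein NUP62 fell by 0.70 (SE 0.15, 0.09 and 0.09). Without doxorubicin replicate 1 the median was -0.10. The camera adjusted p was 0.000658, with adjusted p = 0.287 with an estimated correlation, and 5, 4, 4, 5 and 5 members fell without vehicle replicate 1, 2 or 3 or doxorubicin replicate 1 or 2. The lists of amino acid transporters (2 rose and 2 fell of 37, with the creatine transporter SLC6A8 among those that rose), glycolysis (1 and 2 of 19) and HOX genes (0 and 1 of 24) had camera adjusted p from 0.284 to 0.518. The glycolysis counts were 1 and 1 without vehicle replicate 2, 0 and 2 without vehicle replicate 3, 0 and 3 without doxorubicin replicate 3 and 0 and 1 without any 1 of the other arrays. Of the transporters 1 rose and 1 fell without vehicle replicate 2, 2 and 1 without vehicle replicate 1, 3 and 2 without vehicle replicate 3 or doxorubicin replicate 1, and 2 and 3 without doxorubicin replicate 3. Of 16 aminoacyl-tRNA synthetases 0 rose or fell by limma (0 and 4 unadjusted), with a camera adjusted p of 0.0669, and without doxorubicin replicate 3, 1 rose and 3 fell. IFI27 and IFI6, interferon-induced genes, stood at 10.15 and 10.60 on doxorubicin replicate 2, against 6.62 and 8.23 on replicate 1 and 6.45 and 7.65 on replicate 3. On vehicle replicate 3 the control probe set for the 5′ part of 18S ribosomal RNA stood at 12.11, against 8.14 and 8.17 on the other vehicle arrays. Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave 1808 probe sets, and the highest of the other 9 gave 0 by limma (275 to 1212 at an unadjusted p under 0.05); with 10 splits no share under 0.1 can be reached.

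Of 66 measured splicing factor genes 20 fell and 0 rose (32 and 2 unadjusted), with a median log2 change of -0.24 that became 0.11 when centred on the hybridization controls, a camera adjusted p of 1.01e-10, and adjusted p = 0.0589 with an estimated correlation. HNRNPD fell by 1.42, SRSF3 fell by 1.26 and HNRNPDL fell by 1.13 (SE 0.14, 0.08 and 0.22). Without these 3, which led to the list, the camera p was 5.93e-10 (0.0168 with an estimated correlation). The list was written when the largest changes were known, so this removal does not make its test independent of the data. The 110 brighter zinc finger genes, taken as short-lived, had a median of 0.00 (95% bootstrap interval -0.03 to 0.06). The splicing factors, at -0.24, lay below this, so the zinc finger class did not share their fall. A general loss of short-lived transcripts is not decided by this, since no lifetimes were measured and the classes were not matched on brightness. The number of splicing factor genes that fell was 11 and 8 without vehicle replicates 1 and 2, and 13 without doxorubicin replicate 1. A candidate explanation is a response of splicing factor transcripts to the drug. These arrays do not separate it from a change in the mix of isoforms that the probe sets read. Centring cannot test whether a shift in the scale of all genes is the source of the list's shift relative to other genes. It moves all genes of an array alike, so it leaves that relative shift unchanged by construction. Centred on the hybridization controls, the list median was 0.11 and that of all probe sets 0.37. Whether these transcripts fell in amount depends on that scale and stays open.

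Among 41 estrogen-induced genes 7 were higher and 1 lower with the drug in hormone-depleted cells, and the list had a camera adjusted p of 0.0016 (0.563 with an estimated correlation, and 0.104 by fry). The 3 members shared with the immediate-early list are argued against as the source of that shift. Without them 38 members had a median of 0.20 and a camera p of 0.000576 with the preset correlation. No member is shared with the p53 target list, so p53 targets played no part in this test. What stays open is a shift carried in large part by few arrays: the median of the list lay 0.13, 0.13 and 0.41 above the vehicle mean on doxorubicin replicates 1, 2 and 3, and it was 0.12 without doxorubicin replicate 3 and 0.08 without that array and vehicle replicate 1, the lowest of the 9 fits that left out 1 array of each group, with adjusted p from 3.6e-05 to 0.0486. Leaving out both replicate 3 arrays (adjusted p = 0.000161, median 0.21) does not decide this, since the list lay 0.18 above the other vehicle arrays on vehicle replicate 3 and 0.25 above the other doxorubicin arrays on doxorubicin replicate 3. More hormone on vehicle replicate 3 would lessen such a shift, and the median was 0.26 without that array; an effect of the drug on receptor-dependent transcription may contribute, as a hypothesis that was not tested apart from hormone exposure of the doxorubicin arrays.

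Doxorubicin replicate 3 stood apart from replicates 1 and 2. From their mean 71 genes differed by 1 or more on the log2 scale, where replicates 1 and 2 differed by as much in 9 genes. Of the 71, 49 lay 1 or more from each of them while they differed by less than 1. Among genes at or above the median brightness, HSPB8, SERPINA3 and GAL deviated by 1.75, 1.68 and 1.67. FLRT3, TNS3 and CYP1A1 deviated by -1.91, -1.65 and -1.62. The dimmer PDZK1 deviated by 2.78, to 7.84. Vehicle replicate 3 lay the same way for CYP1A1 (7.01 against 8.11 and 8.07 on vehicle replicates 1 and 2), TNS3 (7.52 against 7.92 and 8.04) and HSPB8 (8.10 against 7.71 and 7.61). A drug response stronger by a common factor over all genes is argued against. The deviation of this array from 1 of the other 2 was regressed on the change that the other of them showed against vehicle. The slope was 0.00701 (mean of both orders, 95% bootstrap interval -0.01 to 0.03 across genes). It cannot exclude a stronger response of some genes beside a weaker one of others. The G2/M list lay 0.55 below the vehicle mean on this array, against 0.93 and 0.88 on replicates 1 and 2. The p53 targets lay 0.97 above that mean, against 0.84 and 0.97. Hormone exposure that differs may contribute, since the estrogen-induced list deviated by 0.25 in the median, above the random range of -0.07 to 0.10, with 26 of 41 members higher and a deviation of -0.56 for ESR1, although MYC, a member, deviated by -0.41. Leukocyte markers lay at percentile 99.89 of such random lists, with the same limit. Their median deviation was 0.19, while stromal, endothelial and basal markers lay inside the range. CORO1A stood at 8.53 against 7.95, CD74 at 7.18 against 6.86 and PTPRC at 5.53 against 5.60. Of the 14 markers 2 reach the median brightness, so other cells stay open for this cultured line. A difference in RNA quality stays open too, since the 3′ minus 5′ difference of ACTB was 0.257 against at most 0.219 on the other arrays, while that of GAPDH, 0.106, lay within their range of 0.084 to 0.167.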
